A study of Mus musculus with 6 samples.

How the data were processed

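Total RNA of sciatic nerves from 3 mutant and 3 control mice, all 25 days old, had been extracted with Trizol, amplified with the Ambion WT Expression kit, labelled with biotin and hybridised to 1-colour Affymetrix whole-transcript arrays, per the labels' protocols. The groups were taken from the genotype in the labels, and the labels call the samples of a group biological replicates. The authors deposited 1 table of log2 values with 1 value per probe set and mouse. The log base is not stated in the sources used here and was read from the values, which ran from 3.55 to 14.52. The submitters' processing notes name limma, without a version or a role. How the background was corrected and how arrays were normalized and summarised is not given in the sources used here, and the array medians of 7.99 to 8.08 lay close together. Arrays have no read depth, and no detection calls were used here, so a low value may be background and the fold change of a gene with a low value in 1 group is compressed. No genome build is given in the sources used here, so no coordinates are printed.

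The table held 21225 gene-level probe sets. The platform annotation, with symbols updated through Entrez gene numbers to the RefSeq annotation of assembly GRCm38.p6, named 20239 of them by 1 symbol each, 0 by several, and left 986 unnamed here. No symbol had more than 1 probe set. The 20239 named genes were tested and the 986 others were tested only in an alternative. The table held 0 columns of samples outside the study.

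Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend, not robust), mutant minus control, without a block, and p-values were adjusted with the Benjamini-Hochberg method over all genes. A gene passed at an adjusted p under 0.05. The moderated test had 6.893 degrees of freedom in all. A fold change is a difference of group means of log2 values, and SE is its moderated standard error. Values per group are mean ± SD. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists with at least 5 measured members. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run as alternatives. The 34 lists held 571 members, of which 532 were measured, and 33 lists were tested. Besides the count over all genes, each list's members were adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

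The comparisons, the 34 lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the alternatives named below as added. Named genes were Zeb2, the 12 largest log2 rises and the 12 largest falls among genes that passed and whose mutant and control values did not overlap, and in each list up to 4 members with the largest change among those that passed, or the member with the smallest p. All sex-linked genes were named. Further members of lists (Mbp, Pmp22, Nkain2, Srebf2, Elovl5, Fasn, Acly, Scd1, Sox2, Egr3, Jun, Sox10, Egr2, Itga1, Scn7a, Shh, Gdnf, Bdnf, Ezr, H2-DMb1, Mki67 and Top2a) were chosen after their values were seen.

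The labels give both groups the replicate numbers 1 to 3, with no statement of what they share. Deviations from the group means, over all genes, correlated between same-numbered samples at 0.36, 0.574 and 0.295. All 3 values were over 0.1, and a fit with the replicate number as a block was an alternative. Mutant 1 and control 3, of different numbers, correlated at 0.303, so these values do not establish a pairing. Over the 13019 genes that did not follow the muscle score the 3 correlations were −0.477, −0.159 and 0.248. The largest correlation between 2 arrays was 0.995 (mutants 1 and 3, of different sex), so no array was treated as a repeat of another.

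Alternatives fixed in advance left out the lowest 25% or 50% of genes by mean value, repeated quantile normalization, centred arrays on their medians, added 16 to the linear values before the logarithm, used a trended robust prior, array weights or the replicate block, tested every probe set, and left out each sample in turn, where the group then had 2 samples. Alternatives chosen after seeing the data used sex, the muscle score or the adipocyte score as a covariate, or left out the 2 muscle-rich samples, mutant 2 and control 2. The scores are the mean log2 values of the muscle and adipocyte lists in a sample, and sex was read from Xist and Y-linked genes.

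The fit and camera were tested on simulated data for 20239 genes, in 20 runs that changed 50 genes by each size. For the comparison of mutant and control, 23.2% of genes changed by 0.5 on the log2 scale were recovered, 75.9% of those changed by 1, 95.1% of those changed by 2 and 98.9% of those changed by 4. Of all calls, 4.03% were genes that had not been changed. The runs changed a smaller share of genes than the 9.62% that passed in the real data, so recovery in the real data may differ. A shifted list was found in 20 of 20 runs. In 640 tests of the other lists, 4 passed among lists that shared no member with the shifted one. The simulated noise was drawn for each gene on its own, whereas the estimated correlation in the real myelin list was 0.762. The runs therefore do not show how often camera passes unshifted lists whose members move together.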

Results

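Gene expression was measured in sciatic nerves of 25-day-old mice on Affymetrix whole-transcript arrays, with 1 array per mouse. The 3 mutant mice carried DhhCre, a Cre recombinase active in the Schwann cell lineage, and 2 floxed alleles of Zeb2, the gene also called Sip1, which encodes a zinc finger transcription factor. The 3 control mice carried the floxed alleles without Cre. The arrays gave log2 values for 20239 named genes, from 3.55 to 14.52, with array medians between 7.99 and 8.08, and the number of arrays limits the precision. The comparison asks which transcripts of the nerve differed between mutant and control mice.

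Zeb2 itself was lower in the mutant nerves, at 10.88 ± 0.19 against 11.75 ± 0.23 on the log2 scale (mean ± SD, n = 3 each), and all 3 mutant values lay below all 3 control values. The difference was −0.88 (SE 0.15, 95% confidence interval −1.23 to −0.52, limma adjusted p = 0.0137). Without mutant 1 the difference was −0.92 and the adjusted p 0.0522. The floxed part of the gene and the position of the probes are not given in the sources used here, and whole nerves hold other cells, so the value does not measure how much of the gene Schwann cells lost.

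Of the 12 genes with the largest falls, 6 were members of the myelin list and 6 were not. Pmp2, the fatty acid-binding protein of peripheral myelin, fell from 12.98 ± 0.13 to 6.40 ± 0.51 (log2 fold change −6.58, SE 0.24, 95.9-fold lower, limma adjusted p = 7.03e-05). Ugt8a, which makes galactocerebroside, fell by 5.03 on the log2 scale. So did Mag, the adhesion molecule of the inner myelin membrane (−4.89), the phosphatase Dusp15 (−4.83), Fa2h, which hydroxylates myelin lipids (−4.45), and Drp2, a dystrophin-related protein of the Schwann cell membrane (−4.34). The 6 outside the list were Septin3 (−4.41), Them5 (−4.39), Serpind1 (−4.22), Vat1l (−4.10), Ddn (−4.09) and Mlip (−3.96). The adjusted p of these 12 genes lay between 6.56e-05 and 0.00932, the highest being that of Mlip, a lamin-interacting protein of muscle. Mlip stood at 10.25 in mutant 2, a muscle-rich sample, against 7.68 and 8.13 in the other mutants, and its log2 fold change without mutant 2 was −4.74.

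The largest rise was that of Gria2, a subunit of AMPA-type glutamate receptors, from 5.90 ± 0.17 to 11.46 ± 0.22 (log2 fold change 5.56, SE 0.14, 47.1-fold higher, limma adjusted p = 5.24e-05). Agr3, of the protein disulfide isomerase family, rose by 4.57 on the log2 scale (SE 0.30), and Gfap, the intermediate filament protein of astrocytes and of immature and nonmyelinating Schwann cells, rose by 4.55 (SE 0.21). Ptprz1, a receptor tyrosine phosphatase, rose by 4.46, Pld5 by 4.21, the small proteoglycan Epyc by 3.997, Prss35 by 3.75, the fatty acid elongase Elovl2 by 3.62 and the ferric reductase Cybrd1 by 3.60. Tecta and Otogl, proteins of the extracellular gels of the inner ear, rose by 3.49 and 3.47, and Hhip, which binds hedgehog ligands, rose by 3.19. The adjusted p of these 12 genes lay between 5.24e-05 and 0.000577. The control means of these genes ran from 5.12 to 8.02, against array medians of 7.99 to 8.08, and array background compresses fold changes at the low end.

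**Figure D1:**
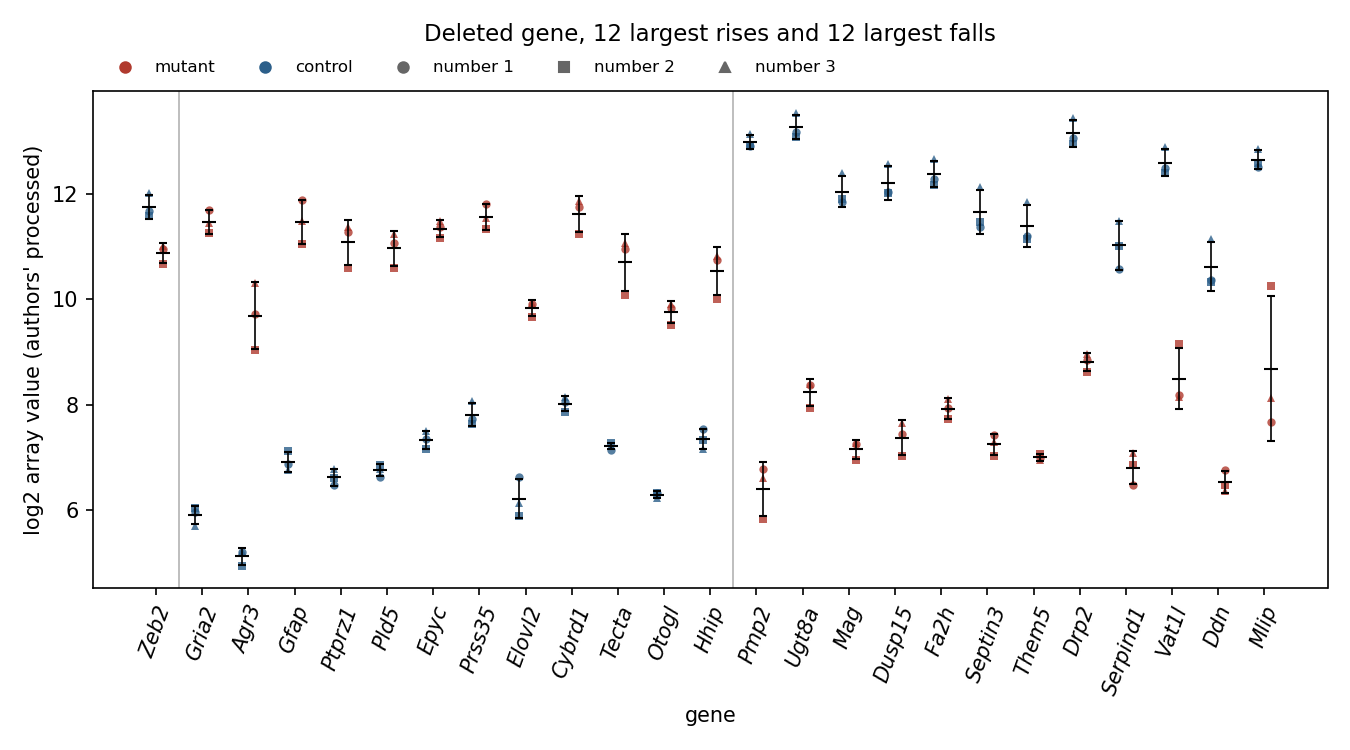
Log2 array values (y axis) of Zeb2, the 12 genes with the largest rise and the 12 with the largest fall (x axis) in each of 3 mutant and 3 control nerves, with bars for the mean ± SD of a group and symbols for the replicate number. Gria2 rises from 5.90 to 11.46 and Pmp2 falls from 12.98 to 6.40, and in each of the 25 genes the mutant and control points do not overlap.

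In all, 1948 of 20239 genes (9.62%) differed, 1161 higher and 787 lower in the mutants, and 683 of them by at least 2-fold, 338 higher and 345 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Each of the 1948 genes had its 3 mutant values on one side of its 3 control values, as had 28.12% of all genes, where chance gives 10%. The count was 896 without mutant 1, with 504 higher and 392 lower, and 910 without mutant 3, with 502 higher and 408 lower. It was 3655 with array weights, with 2411 higher and 1244 lower. The higher genes numbered 742 without control 2, and the lower genes 1189 with the adipocyte score as a covariate and 453 without the 2 muscle-rich samples.

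The nerves held different amounts of other tissue. The mean log2 value of 18 skeletal muscle markers was 7.56, 12.58 and 9.997 in mutants 1 to 3 and 7.66, 12.64 and 10.47 in controls 1 to 3, a range of 33.9-fold that followed the replicate number. The mean of 13 adipocyte markers was 10.85, 11.32 and 10.68 in the mutants and 12.36, 11.46 and 10.13 in the controls. Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty placed 2 males (1 and 2) and 1 female among the mutants, and 2 females (1 and 2) and 1 male among the controls. Xist was 11.90 to 12.13 in the females and 5.44 to 5.62 in the males, and Usp9y differed between the groups by 0.06 (adjusted p = 0.807). The sex-linked list was not shifted as a whole (camera adjusted p = 0.649). With sex as a covariate 1576 genes differed, of which 1475 were among the 1948.

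**Figure D2:**
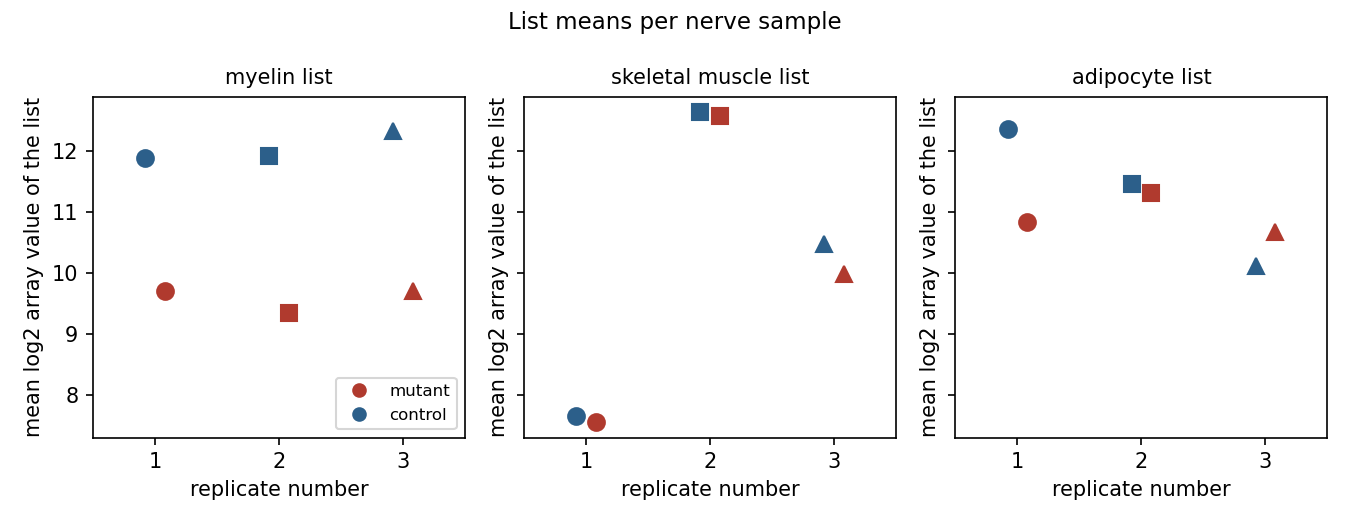
Mean log2 array value (y axis) of the myelin list, the skeletal muscle list and the adipocyte list in each nerve sample, against the replicate number (x axis), with mutants in red and controls in blue. Myelin means are 9.35 to 9.71 in mutants and 11.89 to 12.34 in controls, while muscle means follow the replicate number, from 7.56 to 12.64.

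Genes of myelin fell almost as a whole. Of 23 measured members of the list of myelin structure and maintenance, 21 fell, none rose and 2 did not pass the test, and adjusted over the list alone 21 fell as well. The median log2 fold change was −2.15, and the members ran from Pmp2 at −6.58 to Nkain2 at −0.26. Among the falls of other myelin proteins were those of Mbp (−1.39) and Pmp22 (−0.60). The camera adjusted p was 1.84e-27 with a preset correlation of 0.01, and the adjusted p = 0.282 with an estimated correlation. The fry adjusted p was 0.00213. With an estimated correlation none of the 33 tested lists passed, and with fry 10 passed. The median was −2.40 among males and −1.95 among females, and −1.75, −2.23 and −2.29 between samples numbered 1, 2 and 3.

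Sterol synthesis fell alongside. Of 17 measured members 16 fell, and adjusted over the list alone all 17 did. The median was −1.67 (camera adjusted p = 1.29e-22, 0.282 with an estimated correlation, fry adjusted p = 0.00213). Lss, which closes the first sterol ring system, fell by 2.69 (SE 0.16). The lanosterol demethylase Cyp51 (−2.63, SE 0.23), Hsd17b7 (−2.27) and the sterol reductase Tm7sf2 (−2.26) fell too. The member that did not pass was Srebf2, a transcription factor of sterol synthesis, at −0.55 (adjusted p = 0.0799), which passed with the replicate number as a block (adjusted p = 0.0385).

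In the list of fatty acid and sphingolipid synthesis, 11 of 22 members fell, 1 rose and 10 did not pass. Adjusted over the list alone 12 fell and 1 rose. The median was −0.56 (camera adjusted p = 2.04e-08, 0.282 with an estimated correlation, fry adjusted p = 0.00117). Its members Ugt8a and Fa2h are also on the myelin list, so the shifts of these lists are not independent of each other. Besides Ugt8a and Fa2h, the elongases Elovl7 (−3.79) and Elovl6 (−2.15) fell. The member that rose was another elongase, Elovl5, at 0.94. The median was −0.85 without the 2 muscle-rich samples. Among the members that did not pass were Fasn at −0.24, Acly at −0.48 and Scd1 at −0.02, lipogenic genes that fat cells also express, and the adipocyte score differed between samples by up to 2.23 on the log2 scale.

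Genes of the immature Schwann cell state and inhibitors of myelination were higher. Of 27 members 11 rose, 1 fell and 15 did not pass, and adjusted over the list alone 14 rose and 3 fell. The median was 0.64 (camera adjusted p = 6.75e-06, 0.282 with an estimated correlation, fry adjusted p = 0.00365). Gfap rose most, followed by Hey2, a Notch target, at 3.04, and Ednrb, an endothelin receptor, at 2.44. The transcription factors Sox2 (1.62), Egr3 (1.60), Id2 (1.35) and Jun (1.23) also rose. The member that fell was the adhesion molecule L1cam, at −1.96. With the replicate number as a block, 3 members fell instead of 1, and without control 1, 2 fell. The median was 0.38 without mutant 3.

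Transcription factors and receptors that promote myelination were not shifted as a whole (15 members, 3 higher, 2 lower, 10 not past the test, median −0.09, camera adjusted p = 0.747). The median was −0.18 without control 2, −0.02 without mutant 2 and 0.03 without control 3. Adjusted over the list alone 3 rose and 4 fell. Erbb3, a neuregulin receptor (−1.14) and Pou3f1 (−0.84) fell, while the related factor Pou3f2 rose by 1.03 and the deacetylase Hdac2 by 0.66. Sox10 and Egr2 did not pass, Sox10 at −0.74 (limma adjusted p = 0.0639) and Egr2 at −1.47 (adjusted p = 0.110), but Sox10 passed as lower with the replicate number as a block (adjusted p = 0.0136). The falls of Erbb3 and Pou3f1 did not pass without mutant 1 (Erbb3 adjusted p = 0.0635, Pou3f1 0.0918) or mutant 3 (0.051 and 0.125) or without the 2 muscle-rich samples (0.071 and 0.114), and that of Pou3f1 also not without mutant 2 (0.0709) or control 2 (0.066).

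The markers of nonmyelinating Schwann cells went both ways. Of 9 members Gfap (4.55), Ncam1 (1.44) and Itga1 (1.24) rose, and the adhesion molecules Cadm3 (−2.70) and L1cam (−1.96) and the sodium channel Scn7a (−1.36) fell, while adjusted over the list alone 4 rose and 4 fell. The list was not shifted (median −0.04, mean 0.15, camera direction lower, adjusted p = 0.747), and its median ran from −0.19 without mutant 3 and −0.14 without control 3 to 0.04 without control 1 and 0.09 without mutant 2. Of 16 genes of repair Schwann cells, those of injured nerve, 3 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell (median 0.03, up to 0.07 without mutant 3, camera adjusted p = 0.135). The phagocytic receptor Megf10 rose by 1.49, the cytokine Clcf1 by 1.06 and Sox4 by 0.76, and Uchl1 fell by 0.93. Other repair genes stood near no difference, Shh at 0.26 (limma adjusted p = 0.162), Gdnf at −0.02 (0.932) and Bdnf at 0.04 (0.839). Megf10 did not pass without mutant 1 (adjusted p = 0.0602) or mutant 3 (0.0556). Uchl1 passed only when control 1 was the sample left out, with adjusted p between 0.0507 and 0.0819 without any other sample, and passed neither with sex as a covariate (0.0569) nor without the 2 muscle-rich samples (0.0964).

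Among the genes of the node of Ranvier and paranode, 5 of 15 fell and 1 rose, and adjusted over the list alone 5 fell and 3 rose. Nfasc, the glial and axonal neurofascin, fell by 3.34. The potassium channels Kcna2 (−2.50) and Kcna1 (−1.69) and the nodal protein Gldn (−2.07) fell as well. Ezr rose by 0.75. The median was −0.15 (camera adjusted p = 0.0485, 0.549 with an estimated correlation, fry adjusted p = 0.0202). The camera call was lost without control 2 (adjusted p = 0.0868), control 3 (0.0775) or mutant 2 (0.0967), and without the 2 muscle-rich samples (0.126). It was also lost with array weights (0.0582), median centring (0.0774), a trended robust prior (0.05) or the muscle score as a covariate (0.0517). The rise of Ezr was lost without mutant 1, mutant 3 or control 2, 2 members rose without mutant 2, and 3 rose with the replicate number as a block. Without the lowest 50% of genes the median of the members left was −0.59. Neuronal and axonal transcripts were not shifted (13 members, median −0.10, from −0.15 without mutant 3 to −0.03 without control 3, camera adjusted p = 0.214), with Uchl1 the 1 member that fell, also when adjusted over the list alone, and with none that fell without any one sample other than control 1.

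Notch, BMP and TGF-beta, and Wnt pathway genes were higher as lists. The immature Schwann cell list shares members with the Notch list, Hey2 and Hes1 among them, and with the BMP and TGF-beta list, such as Id2. The shifts of these lists are therefore not independent of each other. Of 15 Notch genes 4 rose and none fell, and adjusted over the list alone 6 rose. The median was 0.20 (camera adjusted p = 0.00612, 0.284 with an estimated correlation, fry adjusted p = 0.00365). The 4 genes were Hey2, the ligand Jag1 (0.84), the modifying enzyme Lfng (0.73) and Hes1 (0.71). Of 19 BMP and TGF-beta genes 7 rose, 9 adjusted over the list alone. The median was 0.34 (camera adjusted p = 7.42e-05, 0.284 with an estimated correlation, fry adjusted p = 0.00687). Genes that rose included Ccn2 (1.64), Tgfb2 (1.40), Id2 (1.35) and Tgfbi (1.20). Of 16 Wnt genes 5 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell. The median was 0.13 (camera adjusted p = 0.0394, 0.549 with an estimated correlation, fry adjusted p = 0.0258). Lgr5 rose by 2.62, Ccnd1 by 1.20 and Wnt6 by 0.72, and Nkd1 fell by 0.98. The Notch median was 0.13 without control 2 and 0.089 without control 3, and the Wnt median 0.082 without mutant 1 and 0.24 without mutant 2. Without mutant 1, mutant 3 or control 2 only 2 Notch genes rose, and without mutant 1 or mutant 3 only 4 BMP and TGF-beta genes. Hes1 did not pass without mutant 1 (adjusted p = 0.111), mutant 3 (0.0981), control 1 (0.0709) or control 2 (0.0689). Lfng did not pass without mutant 1 (0.0739), mutant 3 (0.0755), control 2 (0.0628) or control 3 (0.0564), Tgfb2 without mutant 1 (0.0567) or mutant 3 (0.0581), and Nkd1 without mutant 1 (0.0971) or mutant 2 (0.0614). Without the 2 muscle-rich samples Hes1 (0.0869), Lfng (0.066) and Nkd1 (0.0771) did not pass. Without control 3, 1 BMP and TGF-beta gene fell. The Wnt call of camera was lost without mutant 1 (adjusted p = 0.0601), mutant 3 (0.0572) or control 1 (0.0894), with repeated quantile normalization (0.0637), both filters on low values (0.133 and 0.113) and the adipocyte score as a covariate (0.0836).

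None of 30 mitotic cell cycle genes passed over all genes, and tests of the list as a whole disagreed. Adjusted over the list alone 26 were higher and none lower (median 0.57, camera adjusted p = 1.92e-09, and adjusted p = 0.549 with an estimated correlation, fry adjusted p = 0.110). The helicase subunit Mcm4 had the smallest p (log2 fold change 0.45, limma adjusted p = 0.0515) and passed with array weights (adjusted p = 0.0101), a trended robust prior (0.0477), both filters on low values (0.0428 and 0.0357) and 16 added to the linear values (0.049), and without mutant 2 (0.0247). Mki67 stood at 1.07 (adjusted p = 0.117) and Top2a at 1.13 (adjusted p = 0.120). Over all genes 13 members were higher without mutant 2, 4 without control 1, 4 with the replicate number as a block, 12 with sex, 5 with the muscle score or 2 with the adipocyte score as a covariate, and 6 without the 2 muscle-rich samples. The median was 0.45, 0.28 and 1.02 between samples numbered 1, 2 and 3.

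Markers of other cells of the nerve differed by cell type. Of 10 perineurial markers 6 rose, 8 adjusted over the list alone, and none fell. The median was 0.89 (camera adjusted p = 6.29e-08, 0.282 with an estimated correlation, fry adjusted p = 0.00334). Among those that rose were Moxd1 (2.03, SE 0.078), the tight junction protein Cldn1 (1.53), Casq2 (1.16) and Msln (0.99). Of 18 fibroblast and collagen genes 6 rose, 11 adjusted over the list alone, and none fell (median 0.39, camera adjusted p = 1.05e-06, but adjusted p = 0.549 with an estimated correlation and 0.0777 with fry), among them Lum (0.99), Cd34 (0.74), Fn1 (0.65) and Fbln1 (0.62). Of 24 macrophage markers 2 rose, 5 adjusted over the list alone, and none fell (median 0.37, camera adjusted p = 6.75e-06, but adjusted p = 0.552 with an estimated correlation and 0.110 with fry). These were Lyz1 (0.87) and the cathepsin Ctss (0.80). Without mutant 1 or mutant 3 only 1 fibroblast gene rose, and without control 2 or control 3 only 2, while without mutant 3 only 3 perineurial genes rose. Msln did not pass without mutant 1 (limma adjusted p = 0.0527) or mutant 3 (0.0594). Fbln1 passed only when mutant 2 was the sample left out, with adjusted p between 0.0532 and 0.163 without any other sample. Lyz1 did not pass without mutant 1 (0.122), mutant 2 (0.0731), mutant 3 (0.0657) or control 2 (0.0684). Without the 2 muscle-rich samples Msln (0.0717), Fn1 (0.0535), Fbln1 (0.0537) and Lyz1 (0.121) did not pass, nor did Lyz1 with sex as a covariate (0.0535) or Fbln1 with median centring (0.0571). The macrophage markers that rose numbered 0 without mutant 1, mutant 3 or control 2, 1 without control 3, 8 without control 1 and 4 with the replicate number as a block.

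Endothelial markers were not shifted (16 members, 2 lower, median −0.12, camera adjusted p = 0.0673), and the falls of Vwf (−0.43) and Cldn5 (−0.42), the same 2 as adjusted over the list alone, did not pass with the replicate number as a block (limma adjusted p = 0.0592 and 0.0503) or without the 2 muscle-rich samples (0.116 and 0.0842), nor did Cldn5 with the muscle score (0.0536) or sex (0.0602) as a covariate. When 1 sample was left out, Vwf never passed (0.0576 to 0.133) and Cldn5 passed only without control 2 (0.0468), and 1 member rose without control 1. Without control 3 the endothelial list passed as lower (median −0.27, camera adjusted p = 0.00108), as it did without mutant 1 (0.0414), with repeated quantile normalization (0.0332) and with both filters on low values (0.0393 and 0.0294), while without control 1 its median was −0.03 (−0.025, adjusted p = 0.399). Mural markers (12 members, median −0.03, 0.08 without mutant 3 and 0.04 without control 2, camera direction higher, adjusted p = 0.880) had their smallest p at Acta2 (0.29). Skeletal muscle markers were not shifted (18 members, median −0.23, camera adjusted p = 0.744), with the smallest p at Mb (−0.42), but passed as lower with the replicate number as a block (adjusted p = 0.0367), without control 1 (median −1.57, adjusted p = 0.0182) and with array weights (median −2.80, adjusted p = 0.00361). Their median was 1.15 without control 2 and 1.07 without mutant 1, where they did not pass (adjusted p = 0.211 and 0.198), −1.50 without mutant 2 (0.0727) and −0.14 without control 3. Adipocyte markers were not shifted (13 members, median −0.20, camera adjusted p = 0.451), with the smallest p at Ucp1 (−2.24), but passed as lower without control 3 (median −0.78, adjusted p = 0.000365), and had a median of 0.28 without control 1 (adjusted p = 0.493), −0.11 without control 2, −0.36 without mutant 2 and −0.06 without mutant 3. Ucp1 passed with the adipocyte score as a covariate (−1.43, limma adjusted p = 0.0185). In these 3 lists no member passed, either over all genes or adjusted over the list alone, though 1 mural marker fell without control 3.

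Lymphocyte and granulocyte markers showed no passing member, either over all genes or adjusted over the list alone. The camera adjusted p was 0.481 for 15 T and NK cell markers, 0.318 for 9 B cell markers, 0.0895 for 12 neutrophil markers and 0.520 for 10 mast cell markers. The T and NK cell median, −0.06, was −0.02 without control 1 and −0.09 without control 2, and the B cell median, −0.08, was −0.01 without control 1 and −0.13 without control 2. The smallest p in each was that of Cd247 (−0.15), Cd79a (−0.27), S100a9 (−0.27) and Kit (0.22). The group means of these genes ran from 4.59 (Cd79a in mutants) to 7.98 (Kit in mutants), under every array median. Background may hide a change at such values, so the lack of a call says little about these cells. The neutrophil list passed as lower without control 3 (median −0.11, adjusted p = 0.0308), and the mast cell list as higher with the adipocyte score as a covariate (median 0.18, adjusted p = 0.0215), though the mast cell median was 0.22 without control 1, −0.05 without control 3, 0.0019 without mutant 2 and 0.11 without mutant 3. Of 9 MHC class II genes only H2-DMa fell, by 2.55 (SE 0.25), also when adjusted over the list alone, and the list was not shifted (median 0.02, mean −0.34, camera direction lower, adjusted p = 0.516). With the replicate number as a block H2-DMb1 fell as well (−1.12, adjusted p = 0.0457), and without control 1 or with the adipocyte score as a covariate 2 members fell. The median was −0.05 without mutant 1 and 0.06 without mutant 3. Only 4 erythroid genes were measured, too few for a test of the list, and Hbb-bs, with the smallest p, stood at 0.41 (limma adjusted p = 0.599).

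Of 20 chemokines and cytokines 4 rose and none fell, and adjusted over the list alone 8 rose and 1 fell. Cx3cl1 rose by 1.09, Ccl2 by 1.01, Il33 by 0.87 and Ccl8 by 0.59, and the list did not pass (median 0.10, camera adjusted p = 0.0711), though it did with the replicate number as a block (adjusted p = 0.0487), without control 1 (median 0.22, 0.0252), with array weights (median 0.20, 0.0477), with median centring (0.038) and without the lowest 50% of genes (median 0.68, 0.0294). The median was 0.011 without mutant 1, 0.022 without control 3, 0.055 without control 2, 0.15 without mutant 2 and 0.18 without mutant 3. Without mutant 1, mutant 3 or control 2 only the rises of Cx3cl1 and Ccl8 were kept, Ccl2 passed only when mutant 2 was the sample left out, Ccl2 did not pass with sex as a covariate (adjusted p = 0.0691) or Il33 without control 1 (0.051) or the 2 muscle-rich samples (0.0732), and 1 member fell without control 3 or with the replicate number as a block. Interferon response genes were lower as a list (16 members, median −0.26, camera adjusted p = 0.0289, but adjusted p = 0.773 with an estimated correlation and 0.487 with fry), although only Ifit3 fell, by 0.57, also when adjusted over the list alone. That call was lost without control 1 (adjusted p = 0.0689), control 2 (0.154) or mutant 2 (0.317), without the 2 muscle-rich samples (0.752), with sex as a covariate (0.0984) and with array weights (0.238), and Ifit3 passed only when control 3 was the sample left out, where 3 members fell, and passed neither with sex as a covariate (0.0706) nor without the 2 muscle-rich samples (0.132). The median was −0.13 without mutant 2 and −0.04 (−0.0385) without the 2 muscle-rich samples, and −0.13 with array weights. It was 0.063 among males and −0.367 among females.

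**Figure D3:**
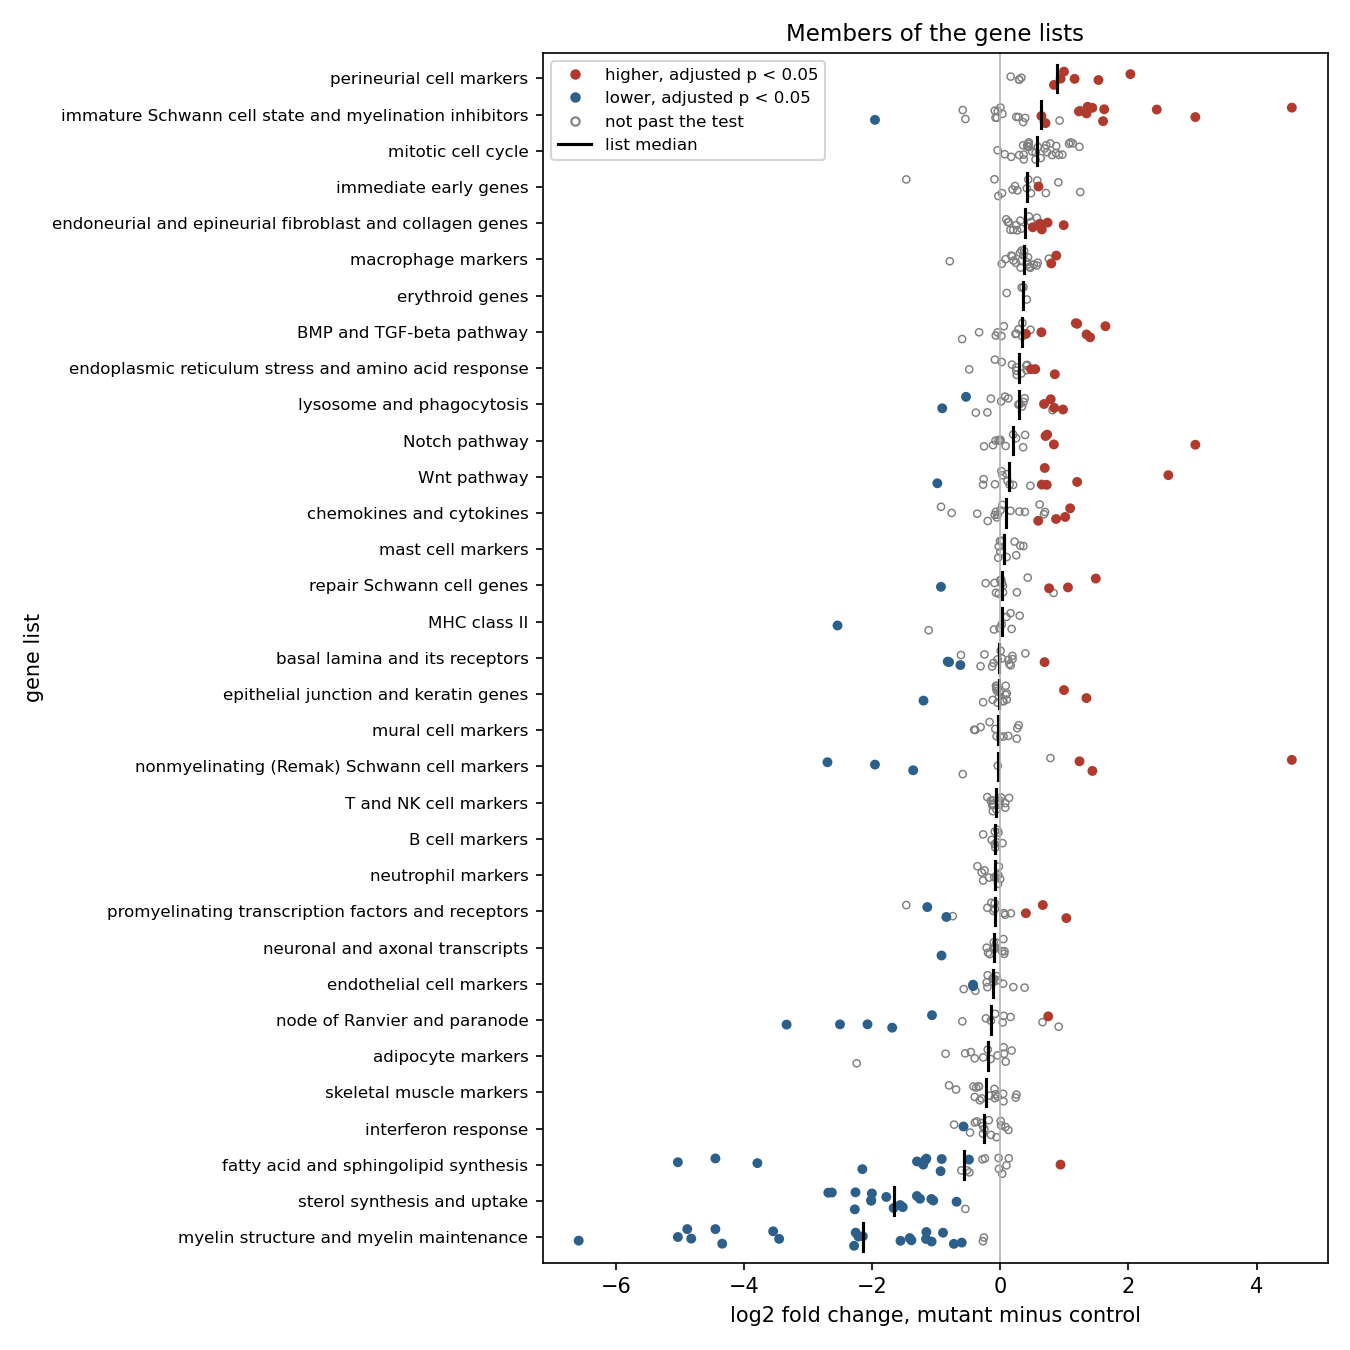
Log2 fold change of mutant minus control (x axis) for each measured member of the gene lists other than the sex-linked one (y axis), ordered by the list median, shown as a black bar, with filled points for members with a limma adjusted p under 0.05. The medians run from −2.15 for myelin to 0.89 for perineurial markers, and muscle, lymphocyte and mast cell markers hold no filled point.

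Genes of endoplasmic reticulum stress and amino acid response were higher (14 members, 3 higher, 6 adjusted over the list alone, none lower). Their median was 0.29 (camera adjusted p = 0.00265, 0.313 with an estimated correlation, fry adjusted p = 0.0244). Sdf2l1 rose by 0.85, the chaperone Hspa5 by 0.55 and Dnajb9 by 0.48, and Dnajb9 did not pass with the replicate number as a block (limma adjusted p = 0.0650), with median centring (0.0711), with sex (0.057), the muscle score (0.0763) or the adipocyte score (0.0596) as a covariate, or, like Hspa5, without the 2 muscle-rich samples (Dnajb9 0.0518, Hspa5 0.0555). None of the 3 passed without mutant 1, control 2 or control 3, Sdf2l1 alone passed without mutant 3, and Hspa5 alone without control 1. Of 18 lysosome and phagocytosis genes 4 rose and 2 fell, and adjusted over the list alone 5 rose and 2 fell (median 0.29, camera adjusted p = 0.0485, but adjusted p = 0.755 with an estimated correlation and 0.110 with fry). Gas6 and its receptor Axl rose by 0.98 and 0.79 and the cathepsin Ctsk by 0.84, while the acid lipase Lipa fell by 0.91. The lysosome call was lost without control 2 (camera adjusted p = 0.156), mutant 1 (0.0988) or mutant 3 (0.0889), without the 2 muscle-rich samples (0.0649), and with both filters on low values (0.168 and 0.248), the adipocyte score (0.0655) or a trended robust prior (0.05), Ctsk did not pass without the 2 muscle-rich samples (limma adjusted p = 0.0647), only 2 lysosome genes rose without mutant 1, mutant 3, control 2 or control 3, and only 1 fell without any one sample other than control 2.

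Immediate early genes were higher as a list (15 members, median 0.41, camera adjusted p = 0.0296, but adjusted p = 0.773 with an estimated correlation and 0.459 with fry), with Dusp1 (0.58) the 1 member that rose, also when adjusted over the list alone. Their mean was highest in mutant 1, at 10.15, and the call was lost without mutant 1 (adjusted p = 0.198), control 1 (0.154) or control 2 (0.111), without the 2 muscle-rich samples (0.06), with sex (0.133) or the adipocyte score (0.107) as a covariate and with both filters on low values (0.106 and 0.248). The median was 0.20 without mutant 1 and 0.63 with array weights. Between samples numbered 1, 2 and 3 it was 0.828, 0.367 and −0.036. Dusp1 itself passed only when mutant 3 was the sample left out, and did not pass with median centring (limma adjusted p = 0.0578), with sex (0.0788) or the muscle score (0.0582) as a covariate, or without the 2 muscle-rich samples (0.142).

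Epithelial junction and keratin genes, some of which Zeb2 represses in other tissues, were not shifted (19 members, median −0.02, from −0.04 without control 2 to 0.01 without mutant 1, mean 0.04, camera direction higher, adjusted p = 0.968). Ocln rose by 1.34 and Krt19 by 0.99, and Cdh1, the epithelial cadherin, fell by 1.20, the same 3 genes as adjusted over the list alone. The fall of Cdh1 did not pass without the 2 muscle-rich samples (limma adjusted p = 0.0606). Basal lamina genes and their receptors were not shifted either (18 members, 1 higher, 3 lower, median −0.02, from −0.09 without mutant 1 to 0.08 without mutant 2, camera adjusted p = 0.649), and adjusted over the list alone 2 rose and 4 fell. Lamb2 rose by 0.69, while Itga6 (−0.80), Utrn (−0.82) and Lamb1 (−0.62) fell. Only 1 of the 3 falls was kept without any one of the mutants, Lamb1 did not pass without any one sample (adjusted p = 0.0570 to 0.128), and Utrn had adjusted p of 0.0696, 0.0577 and 0.0854 without mutants 1 to 3. Neither passed without the 2 muscle-rich samples (Lamb1 0.107, Utrn 0.0778), nor did Lamb1 with sex as a covariate (0.0515). Without mutant 2, 2 members rose.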

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

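In this part, both tests of the muscle pattern were chosen after the result was seen. The fit of other splits of the samples was planned, but how to read it was written after the result was seen. The 986 probe sets without a name here lie outside the comparisons of named genes. In the limma fit of every probe set, 105 of them passed, 55 higher and 50 lower in the mutants, or 10.65% against 9.63% of the named ones.

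The real grouping of the 6 nerves gave 1948 genes, and the highest count among the other 9 ways of dividing them was 4, from the division by sex. The 10 splits in all are too few for a share under 0.05. Like the real grouping, 3 other splits part all 3 pairs of same-numbered samples, and they gave 4, 0 and 0 genes.

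The myelin list had a median log2 fold change of −2.15. A lower share of Schwann cells as the whole cause was examined in 10 genes that Schwann cells of any kind express. Their median was −0.10, no lower than −0.19 (−0.1902) without any 1 sample, while a fall 0.5 times that of myelin would be −1.07. It was −0.485 among males and 0.009 among females, and the members ran from −1.53 to 1.23. Erbb3 and Sox10 are also on the promyelinating list and Cdh19 on the immature list, so their level per cell may differ. The median argues against a lower share as the whole cause only if that level held, which was not tested. Among the 10 genes Art3, S100b and Erbb3 fell and Sox8 rose, and Sox10 fell with the replicate number as a block. A smaller loss therefore stays open as part of the cause. The medians of other cell types moved apart, from −0.12 for endothelial to 0.89 for perineurial markers. This leaves aside muscle (−0.23) and adipocyte (−0.20) markers. Their medians changed sign when 1 sample was left out, but so did those of mural and mast cell markers, which were kept. Unequal muscle is argued against, since the mean muscle score differed between the groups by only −0.21, against a range of 5.08 over the samples. With scores so balanced, the 100.3% of the myelin median kept with the muscle score as a covariate adds little. Unequal sex is argued against, since the myelin median kept 102.4% of its size with sex as a covariate. Perineurial (0.89), fibroblast (0.39) and macrophage (0.37) medians were higher, and how far a changed mix of cells contributes was not settled. A change within the mutant Schwann cells was not tested here.

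Skeletal muscle transcripts differed by 33.9-fold between samples. Each muscle marker followed the mean of the others with a median correlation of 0.985 over the 6 samples (0.9853, lowest 0.578), consistent with muscle tissue taken along with the nerve. The genotype is argued against as the cause of this range, since the group means differed by only 0.043 of the smaller range within a group, and a small difference between the groups stays open. What else same-numbered samples share, such as a dissection day, stays open and was not tested.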

How the results depend on the processing

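The covariates for sex, muscle and adipocyte score and the fits without the 2 muscle-rich samples were chosen after seeing the data. Of the 1948 changed genes, 1475 were also called with sex, 1657 with the muscle score and 1877 with the adipocyte score as a covariate, and 1155 without the 2 muscle-rich samples. No called gene named here and no called list median reversed, while the medians of some lists that did not pass changed sign. For 105 named genes, 1828 of 1977 values under alternatives stayed on the same side of the threshold, 142 lost the call and 7 gained it; for the medians of 38 lists, 698 of 788 stayed, 63 lost the call and 27 gained it. The number of shifted lists was 16 with the preset correlation, 10 with fry and 0 with an estimated correlation, where 0 of 33 passed. Array weights, which gave mutant 1 a weight of 4.81 and mutant 2 one of 0.46, raised the changed genes to 3655, the higher ones to 2411 and the lower ones to 1244. The lower genes numbered 1189 with the adipocyte score as a covariate and 453 without the 2 muscle-rich samples, 4 samples in all; the cause was not tested. Leaving out 1 sample gave 896 to 2021 changed genes, 502 to 1397 higher and 392 to 744 lower. Fewer samples lower the power, which does not account for the 2021 genes without mutant 2, above the 1948 of all samples. The Zeb2 log2 fold change with 1 sample left out ran from −0.97 to −0.74, with an adjusted p of 0.0522 without mutant 1. The replicate block gave 2047 genes, of which 1733 were among the 1948; it changed the calls of the chemokine and muscle lists, ended those of Vwf, Cldn5 and Dnajb9 and gave calls to Srebf2, Sox10 and H2-DMb1, as given beside them, and changed no other call of a list or of a gene named here. Over all list members 22 genes gained a call and 6 lost it. Centring arrays on their medians moved the higher share of changed genes from 59.6% to 52.1% and the median log2 fold change of all genes from −0.02 to −0.07. The mean of a symbol's probe sets was not run, since no symbol had more than 1. Signal over background limits the genes near the low end of the arrays, whose fold changes are compressed; leaving out the lowest 50% of genes gave 1877 changed genes among 10120.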

Other observations

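The lists in this part were written after the genes with the largest changes had been seen and before any other member was looked up, and they leave out the genes already seen; named members were chosen after their values were seen. Several genes better known from astrocytes and synapses were higher in the mutant nerves. Of 21 astrocyte genes 8 rose, 1 fell and 12 did not pass the limma test, and adjusted over the list alone 9 rose and 1 fell (median 0.26). The glutamate transporters Slc1a3 and Slc1a2 rose by 2.37 and 0.85, the aldolase Aldoc by 1.26 and the gap junction protein Gja1 by 1.07, while Hepacam fell by 1.24, and Aqp4 stood at −0.35 (adjusted p = 0.890) and Sox9 at −0.01 (adjusted p = 0.988). Of 24 genes of synaptic adhesion and glutamate receptors 6 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell (median 0.24). The kainate receptor subunits Grik3 and Grik2 rose by 2.58 and 1.75, the adhesion molecule Slitrk2 by 1.76, the cadherin Cdh6 by 1.51 and the AMPA receptor subunit Gria1 by 1.38, and Lrrtm3 fell by 1.35. Without mutant 1 or mutant 3 only 4 astrocyte genes rose, no astrocyte gene fell without any one sample other than control 1, and 2 synaptic genes fell without control 1.

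A hypothesis was that genes of central glia and neurons rise as classes. The astrocyte list was shifted higher (camera adjusted p = 0.0155 over the 5 added lists, 0.00619 before adjustment), and so was the synaptic list (adjusted p = 0.0103, 0.00206 before adjustment). With an estimated correlation the camera adjusted p was 0.371 for both. With fry the adjusted p was 0.0138 for the astrocyte list and 0.0271 for the synaptic list. The astrocyte call of camera was lost without control 3 (median 0.026, adjusted p = 0.0639) and without the lowest 50% of genes (median 0.72 of the members left, adjusted p = 0.130). The astrocyte median was 0.49 without control 2, 0.15 without mutant 2 and 0.14 with array weights, and the synaptic median 0.41 and 1.14 without the lowest 25% and 50% of genes. Tectorial membrane and cochlear matrix genes other than Tecta, Otogl and Epyc did not follow (10 genes, none past the limma test over all genes or adjusted over the list alone, median −0.08, −0.13 without control 3 and 0.01 without control 1, camera adjusted p = 0.277, the same before adjustment). Central nervous tissue in the mutant samples is argued against, since the medians were −0.10 for neuronal transcripts (from −0.15 without mutant 3 to −0.03 without control 3) and −0.09 (−0.0873) for 11 oligodendrocyte genes, of which 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0767, below 0.05 without control 1 or mutant 1, at 0.0347 and 0.0459, and with sex or the adipocyte score as a covariate or the lowest 25% left out, at 0.0362, 0.0375 and 0.0371, with fry at 0.0311, and with only 1 gene lower without mutant 1 or mutant 3). The oligodendrocyte median is weaker evidence, since members ran from −1.54 to 1.23 and falls in the nerve's own cells could offset a gain. Which cells of the nerve carry the higher astrocyte and synaptic transcripts was not tested, so a change within Schwann cells may be one source among others.

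Of the 10 Schwann cell lineage genes, Art3 (−1.53), S100b (−1.51) and Erbb3 (−1.14) fell, Sox8 rose by 1.23, and Cdh19 stood at 0.03, Foxd3 at 0.03 and Sorcs1 at 0.01. Erbb3 did not pass without mutant 1 (limma adjusted p = 0.0635) or mutant 3 (0.051) or the 2 muscle-rich samples (0.071). Sox10 passed as lower with the replicate number as a block (0.0136). Adjusted over the list alone 1 rose and 4 fell, and over all genes 2 rose without control 3. The list did not pass (camera adjusted p = 0.0828), but passed as lower without mutant 1 (0.0459), mutant 3 (0.0407) or control 1 (0.0220) and with sex (0.0391) or the adipocyte score (0.0164) as a covariate, where its median stayed between −0.17 and −0.11. It was −0.01 without control 3, −0.05 without mutant 2 and −0.19 without control 2.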
